A study of Mus musculus with 2 samples.

How the data were processed

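The series holds 2 RNA-seq libraries from the mouse, both of 1 group. Per the labels, pancreata were taken whole from NGN3-EGFP embryos at e15.5, dissociated, and sorted for GFP-positive cells, and RNA was extracted with a column kit for small samples. The labels number the samples 1 and 2. Nothing says that they came from separate litters, so the spread between them measures only these samples and may be technical. With 1 group no comparison between conditions could be made, and no paired analysis applies.

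The deposited files hold raw read counts per gene symbol, as whole numbers, with 1 file per sample and 23284 symbols in each. The submitters' processing notes name FastQC, cutadapt, TopHat2 2.0.4, Cufflinks 2.0.2 and DESeq and the mouse build mm9, without their roles or order. The program that made the counts, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense pairs are therefore uncertain. Replicate 1 had 12495143 counted reads and replicate 2 had 12043734. A count of 0 allows up to 3 counts as a one-sided 95% limit, which is 0.241 CPM in replicate 1 and 0.248 CPM in replicate 2. Intervals for single libraries are exact two-sided Clopper-Pearson intervals at 95%. For a count of 0 their upper end is 0.3 CPM in each library. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

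Counts were scaled for library size to CPM with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.9956 and 1.0044. Values are given as mean ± SD over the 2 libraries. A gene was called detected at 1 CPM or more in each library. Log2 values used a prior count of 2, and genes with at least 10 reads over both libraries, 13416 in all, entered the correlations and tests. The spread between replicates was summarised as edgeR's common dispersion with an intercept only, given as its square root, the biological coefficient of variation. Reads of each gene were compared between the libraries with a two-sided exact binomial test given the TMM-scaled library sizes, with Benjamini-Hochberg adjustment at 0.05. That test compares these 2 libraries, not conditions. An exact permutation of 2 paired libraries cannot give a p below 0.5, so orders of genes and lists within a library are given as values in each library. Log2 ratios between libraries are replicate 2 over replicate 1.

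Before the data were examined, 24 gene lists with 343 symbols were fixed, of which 3 symbols were not matched. For 16 lists with at least 5 members of at least 10 reads, the median log2 ratio was placed as a percentile among 10000 random lists matched on mean expression in 20 bins, as a description of these libraries. The genes to name were also fixed by rule: Neurog3; up to 5 members of each list with the highest mean; any member at or above 1 CPM of the lists of endocrine transcription factors, hormones, semaphorin receptors and Notch genes; the 10 most abundant genes; the 5 largest log2 ratios in each direction among genes with a mean of at least 50 CPM and an adjusted p under 0.05; and members below 1 CPM in both libraries of the lists of endocrine transcription factors, hormones and mature beta cell genes. Genes outside this rule are said to be chosen after their values were seen. Some genes that meet the rule are not reported here; they stay in the counts and medians of their lists.

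The reference used here is GENCODE M21 on GRCm38, not mm9, so no coordinates are given and it served only for exon lengths, GC content and 25-base words shared between genes; 22748 symbols, or 97.7%, were matched. Exon lengths, GC content and the genes' own words come from the basic transcript set. This set was chosen after a first run with the full annotation had been seen, because the full set adds retained introns to the exon length of genes such as Gapdh. Results from both sets are given in the closing section, including a test whose outcome depended on the choice.

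The alternatives fixed before the data were examined were plain column totals, DESeq2 1.42.0 size factors, other detection limits of 0.5 and 5 CPM, other count filters, a prior count of 0.5, a trended dispersion, leaving out the 10 most abundant genes from the totals, reads per kb of exon, and leaving out each replicate. Added after seeing the data were Rn45s left out of the totals, the mesenchymal list without its collagen genes, and reads per kb with the full annotation. The dispersion estimate and the binomial test were tested on simulated data. With 13416 simulated genes all made with the same coefficient of variation of 0.5, the estimate was 0.497. In the data the spread fell with level, so this does not show that 1 value describes all genes. In simulated Poisson counts for 13416 genes, the binomial test called 90 of 100 genes changed 2-fold, 97 of 100 changed 4-fold and 9 of 13216 unchanged genes; this simulation holds counting error alone and none of the spread between replicates. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.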

Results

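Gene expression was measured by RNA-seq in GFP-positive cells sorted from the pancreas of NGN3-EGFP mouse embryos at e15.5. Per the series' title these are endocrine progenitor cells of the pancreas. Each library pools the sorted cells, so levels and ratios of genes are averages and do not show which cells held a transcript. The 2 libraries, replicates 1 and 2 of the only group, held 12495143 and 12043734 counted reads. At least 1 read was counted for 13454 genes in replicate 1 and 14204 in replicate 2, and 10651 genes reached 1 CPM in both.

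Transcripts of the transcription factors that drive endocrine differentiation were abundant. Neurog3, the factor that starts the endocrine programme, was at 643 ± 130 CPM (SD, n = 2). The labels do not say whether the NGN3-EGFP reporter replaces a Neurog3 allele, which would bear on this level and on each ratio to Neurog3. Of 30 endocrine transcription factors measured, 29 reached 1 CPM in both libraries and 21 had a mean of at least 100 CPM. Among the highest were Insm1 at 950 ± 110 CPM, Tox3 at 902 ± 26.3 CPM and Nkx2-2 at 691 ± 142 CPM (SD, n = 2 each). Myt1, Pax6, Isl1 and Neurod1 were at 621 ± 158, 605 ± 34.0, 509 ± 11.7 and 442 ± 40.7 CPM. Pax4, a factor of the beta cell lineage, was at 182 ± 42.2 CPM. Pdx1 and Nkx6-1, which act in pancreatic progenitors and beta cells, were at 150 ± 20.2 and 166 ± 38.7 CPM. No read of Insm2 was counted in either library. By the one-sided limit for counting error alone this allows up to 0.241 CPM in replicate 1 and 0.248 CPM in replicate 2.

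Within each library Neurog3 was above Sox9, a factor of the embryonic ductal epithelium, by 8.34-fold in replicate 1 and 6.28-fold in replicate 2. It was above Pax4 by 4.85-fold and 2.61-fold and above Neurod1 by 1.56-fold and 1.33-fold. Per kb of exon the mean ratio was 19.4-fold to Sox9, 3.16-fold to Pax4 and 2.56-fold to Neurod1, against 7.23, 3.56 and 1.44 by CPM. Neurog3 lay below Insm1 in both libraries, with log2 ratios of -0.48 and -0.66, but above it per kb of exon, with a log2 ratio of 0.44. Orders of genes by CPM are not corrected for length, and with 2 libraries no exact test of an order can go below p = 0.5.

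Hormone transcripts were among the most abundant in the sorted cells, and 10 of 10 measured hormone genes reached 1 CPM in both libraries. In pooled cells these levels cannot show whether cells with Neurog3 transcripts also held hormone transcripts. Gcg, which encodes proglucagon, was at 19064 ± 7079 CPM, and the insulin genes Ins1 and Ins2 were at 10388 ± 2844 and 5783 ± 959 CPM (SD, n = 2). Gcg was above Ins1 by 1.68-fold in replicate 1 and 1.94-fold in replicate 2, and Ins1 was above Ins2 by 1.64-fold and 1.92-fold, with mean ratios per kb of exon of 1.76 and 2.19 (1.80 and 1.77 by CPM). Iapp (islet amyloid polypeptide) was at 2984 ± 198 CPM, Pyy (peptide YY) at 2679 ± 272 CPM and Ghrl (ghrelin) at 1582 ± 229 CPM. Sst (somatostatin), Gast (gastrin), Ppy (pancreatic polypeptide) and Npy (neuropeptide Y) were lower, at 693 ± 116, 536 ± 11.1, 159 ± 1.35 and 71.4 ± 1.53 CPM. Ins1 and Ins2 share part of their sequence, and 93.6% and 95.3% of their 25-base words were found in no other gene.

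**Figure D1:**
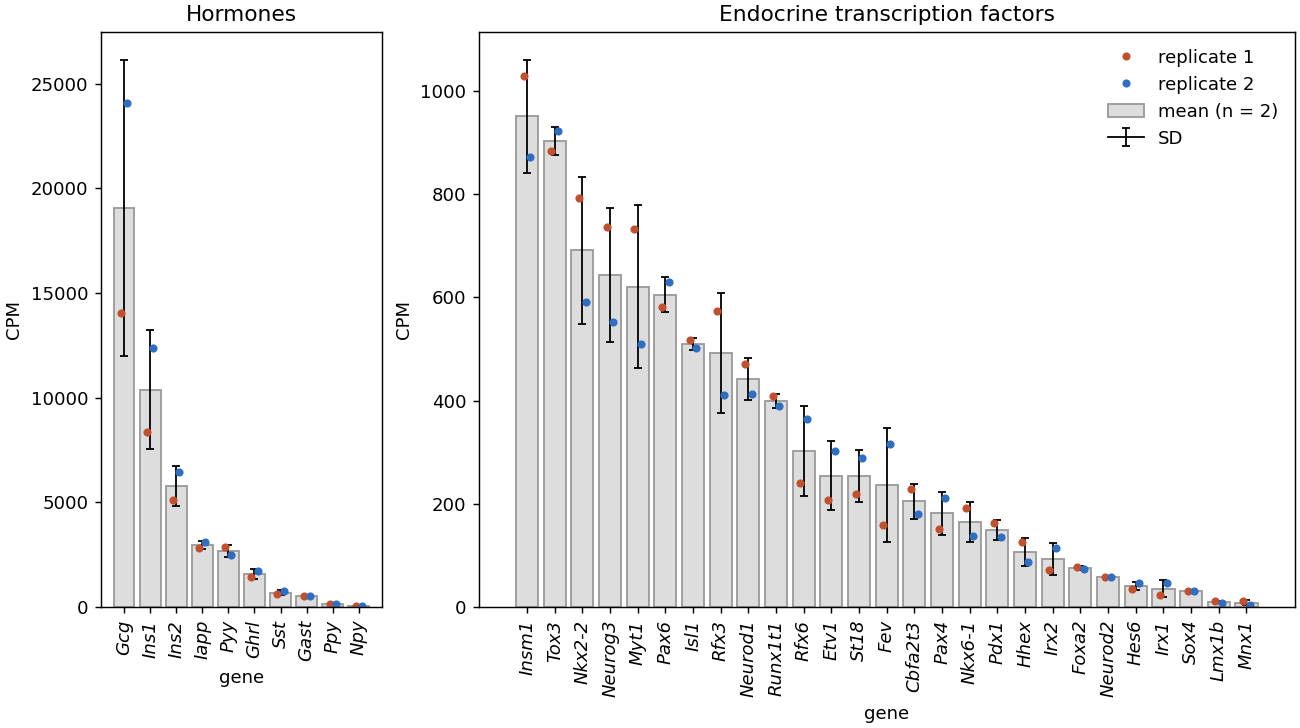
CPM of the hormone genes (left) and of endocrine transcription factors at or above 1 CPM that are reported here (right) on linear axes; bars are means of 2 libraries, error bars are SD, and points are replicate 1 (orange) and replicate 2 (blue). Gcg leads the hormones at 19064 CPM, and Insm1 is at 950 CPM among the transcription factors.

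Genes of dense-core granules, prohormone processing and exocytosis were detected throughout, with 24 of 24 at or above 1 CPM in both libraries. Chgb, a granin, was at 5584 ± 286 CPM, and Cpe, the carboxypeptidase that trims prohormones, at 2900 ± 760 CPM (SD, n = 2). Abcc8, the sulfonylurea receptor subunit of the ATP-sensitive potassium channel, was at 1212 ± 16.9 CPM. Of 9 genes tied to mature beta cells, 8 reached 1 CPM in both libraries. Ero1lb, Sytl4 and G6pc2 were at 350 ± 7.15, 228 ± 96.6 and 138 ± 45.8 CPM. Mafa, a factor of mature beta cells, was chosen after its values were seen and was at 2.81 CPM in replicate 1 and 0.66 CPM in replicate 2. Glp1r, the receptor of glucagon-like peptide 1, was at 17.2 CPM in replicate 1 (exact Clopper-Pearson 95% interval 14.97 to 19.7) and at 145 CPM in replicate 2 (139 to 152). Of 24 genes mutated in human monogenic diabetes, a list that shares members with the lists above, 22 reached 1 CPM in both libraries.

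The sorted cells held far more endocrine transcripts than transcripts of other cell types. The 64 members of the 3 endocrine lists had a median of 287 CPM in replicate 1 and 355 CPM in replicate 2. This was 5.1-fold and 5.8-fold above the list of embryonic ductal epithelium, 66.0-fold and 64.1-fold above the acinar list, and 40.5-fold and 148-fold above the mesenchymal list. The acinar median is uncertain, since some members share most of their 25-base words with other genes. For Try4 and Prss1, 12.1% and 25.5% were found in no other gene. By share of all reads the acinar list was above the ductal list, at 0.264% and 0.185% in replicates 1 and 2 against 0.09% and 0.087%. The medians of the endothelial, immune, erythroid, liver and gut lists were at or under the limit of 3 counts in both libraries. By that limit the endocrine median was at least 1188-fold above each in replicate 1 and at least 1431-fold in replicate 2. The limit covers counting error only, so these folds do not bound the true difference. Sox17 of the endothelial list, for example, was at 0 CPM in replicate 1 and 6.61 CPM in replicate 2. For neural crest and enteric neurons the endocrine median was, by the same limit, at least 1188-fold above in replicate 1, and it was 716-fold above in replicate 2. With members of at least 10 reads only, the difference of median log2 CPM was 2.73 for the gut list, 6.10 for the immune, 6.60 for the liver, 7.29 for the endothelial, 7.62 for the erythroid and 5.05 for the acinar list. Per kb of exon the difference from the acinar list was 4.50, against 5.97 by CPM.

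Of the ductal list, 11 of 13 genes reached 1 CPM in both libraries, with Krt7 at 225 ± 29.9 CPM, Muc1 at 168 ± 30.0 CPM and Sox9 at 88.0 ± 0.22 CPM (SD, n = 2). All 11 epithelial genes did, led by Cdh1 (E-cadherin) at 687 ± 105 CPM and Epcam at 343 ± 46.5 CPM. Of the acinar list, 15 of 29 did. Its highest members were transcripts of digestive enzymes and their cofactors: Ctrb1 (chymotrypsinogen) at 1153 ± 237 CPM, Pnliprp1 at 365 ± 120 CPM, Clps (colipase) at 236 ± 147 CPM and Cpa1 (a carboxypeptidase) at 193 ± 14.97 CPM. Of the mesenchymal list, 8 of 19 did, while 14 did in replicate 1 and 10 in replicate 2 taken alone, with Dlk1 at 144 ± 46.1 CPM and Fn1 (fibronectin) at 129 ± 27.0 CPM.

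Few genes of the following lists reached 1 CPM in both libraries: 1 of 12 endothelial, 2 of 12 immune, 2 of 11 erythroid, 1 of 10 neural crest and 1 of 8 liver genes. In replicates 1 and 2 taken alone these counts were 2 and 3 endothelial, 3 and 3 immune, 3 and 3 erythroid, 1 and 3 neural crest and 2 and 2 liver genes. These included Laptm5 at 20.8 ± 24.3 CPM and Cd68 at 13.1 ± 7.58 CPM among immune genes and Eng at 7.70 ± 8.20 CPM among endothelial genes (SD, n = 2). Alb, which encodes albumin, had no read. Hba-a1, an alpha globin gene, also had none, but only 26.5% of its 25-base words were found in no other gene, so its count is uncertain. Of 8 gut genes 2 did, Vil1 at 51.5 ± 14.4 CPM and Pyy, which is also in the hormone list.

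**Figure D2:**
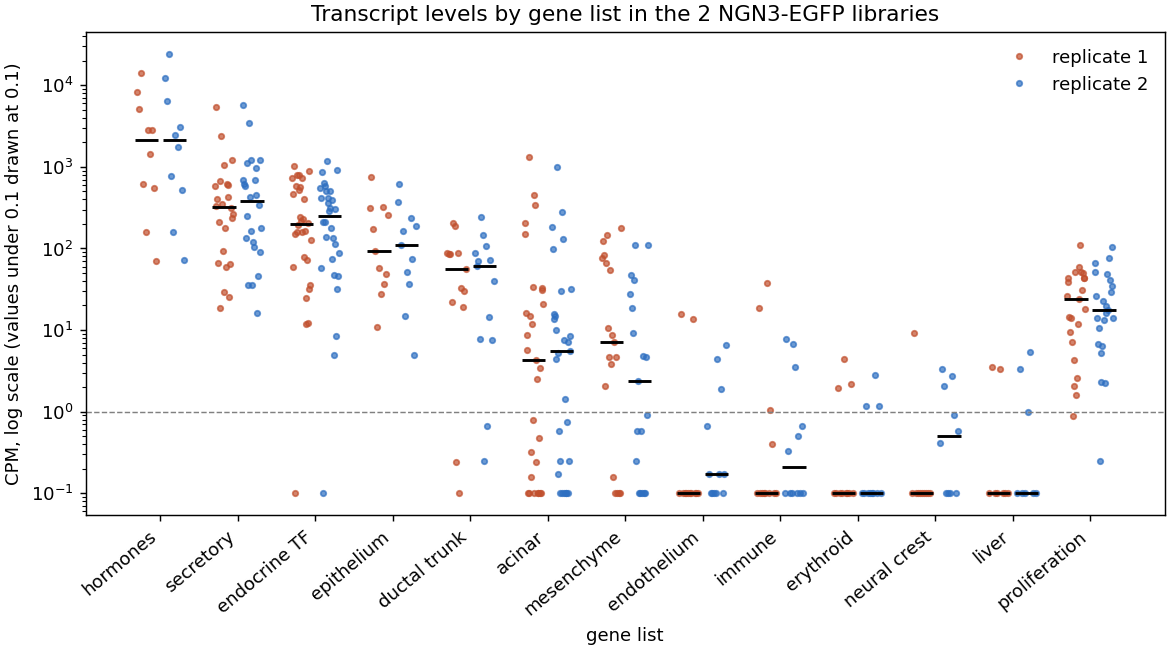
CPM of each measured member of 13 gene lists on a log axis, with replicate 1 in orange and replicate 2 in blue; black lines are list medians, the dashed line is 1 CPM, and values under 0.1 are drawn at 0.1. The endocrine lists lie highest, with a hormone median of 2130 CPM, against 5.28 CPM for the acinar list and 4.38 CPM for the mesenchymal list, each over the mean of the libraries. The black lines are drawn per library, for the mesenchymal list at 7.07 CPM in replicate 1 and 2.40 CPM in replicate 2.

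Of 23 cell cycle genes, 21 reached 1 CPM in both libraries, and the list median was 21.8 CPM. Tyms (thymidylate synthase) was at 73.2 ± 42.7 CPM and the replication helicase subunits Mcm3 and Mcm4 were at 64.5 ± 66.0 and 64.2 ± 17.4 CPM (SD, n = 2). Of 7 cyclin-dependent kinase inhibitors, 3 reached 1 CPM in both libraries. Cdkn1a (p21) was at 685 ± 32.2 CPM, above Cdkn1c (p57) at 59.1 ± 0.30 CPM and Cdkn1b (p27) at 26.8 ± 17.4 CPM.

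Of 20 Notch pathway genes, 14 reached 1 CPM in both libraries. Mfng, which modifies Notch receptors with sugars, was at 71.1 ± 12.9 CPM, the target gene Hes1 at 47.6 ± 11.6 CPM, the transcriptional effector Rbpj at 45.4 ± 9.65 CPM and the receptor Notch1 at 43.2 ± 20.9 CPM (SD, n = 2). The ligand Dll1 was at 4.26 CPM in replicate 1 (exact Clopper-Pearson 95% interval 3.19 to 5.57) and 48.8 CPM in replicate 2 (44.9 to 52.9). Of 11 semaphorin receptors, 8 reached 1 CPM in both libraries. The plexins Plxnb2 and Plxnb1 were at 278 ± 43.0 and 234 ± 39.7 CPM, and the neuropilins Nrp2 and Nrp1 at 8.92 ± 3.40 and 5.71 ± 0.69 CPM. Of 20 semaphorins 11 did, led by Sema6d at 136 ± 39.3 CPM and Sema6a at 125 ± 35.1 CPM. Of 15 genes of Slit, netrin and their receptors 10 did, led by the receptor gene Neo1 at 555 ± 90.2 CPM.

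Of 15 immediate early genes, which respond within minutes to stimulation and to cell handling, 14 reached 1 CPM in both libraries. Egr1 was at 1052 ± 66.3 CPM, Jun at 317 ± 104 CPM and Fos at 227 ± 90.8 CPM (SD, n = 2). All 13 housekeeping genes did, led by Actb at 1800 ± 19.9 CPM and Ywhaz at 1755 ± 44.1 CPM. Of 5 sex-linked genes 1 did, although 4 did in replicate 1 alone: Xist, the RNA of the inactive X chromosome, was at 3281 ± 991 CPM. The Y-linked gene Kdm5d was at 20.1 CPM in replicate 1 (exact Clopper-Pearson 95% interval 17.7 to 22.8) and 0.17 CPM in replicate 2 (0.02 to 0.60). The Y-linked genes Eif2s3y and Uty were also higher in replicate 1, at 9.24 and 1.85 CPM against 0.66 and 0.41 CPM. Ddx3y was not, at 0.08 CPM in replicate 1 and 0.41 CPM in replicate 2. The most abundant transcript of all was Rn45s, the ribosomal RNA precursor, at 45081 ± 11208 CPM. Malat1, a nuclear long noncoding RNA, was at 15469 ± 884 CPM, Peg10 at 10145 ± 838 CPM and Gnas, which encodes a G protein alpha subunit, at 7429 ± 523 CPM.

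The replicates were close for abundant transcripts and far apart for scarce ones. The 58 genes above 1000 CPM had a replicate SD of 0.20 in log2 CPM, and none differed over 2-fold between the libraries. The SD was 0.47 for the 2269 genes from 100 to 1000 CPM, 1.26 for the 6762 from 10 to 100 CPM and 2.25 for the 3487 from 1 to 10 CPM, where 12.2%, 42.9% and 74.0% differed over 2-fold. Levels under 100 CPM are therefore uncertain for single genes. Over 13416 genes the Pearson correlation of log2 CPM was 0.717 and Spearman's rho 0.816, both across genes, which are not independent replicates. The biological coefficient of variation was 0.935.

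By the exact binomial test with Benjamini-Hochberg adjustment, 11468 of 13416 genes, or 85.5%, differed between these libraries beyond counting error, 5895 higher in replicate 2 and 5573 higher in replicate 1. Of these 6394 also differed over 2-fold, so the files do not hold 1 library deposited more than once. Among genes with a mean of at least 50 CPM the largest differences toward replicate 1 were Atad2, at 107 and 0.50 CPM in replicates 1 and 2, Tiam1 at 108 and 2.23 CPM, Akap12 at 172 and 4.71 CPM, Vwde at 155 and 4.71 CPM and Gabpb1 at 119 and 7.44 CPM. Those toward replicate 2 were 6330439K17Rik at 3.05 and 102 CPM, 4933407H18Rik at 3.62 and 112 CPM, Gcnt1 at 5.31 and 102 CPM, Isoc1 at 14.2 and 206 CPM and Lrfn3 at 7.48 and 105 CPM.

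Of the 16 lists, 2 had a median log2 ratio outside the central 95% of matched random lists, where 0.8 would be outside by chance. Mesenchymal transcripts were lower in replicate 2, with a median log2 ratio of -1.48 at percentile 0.13, and 13 of 17 members were higher in replicate 1. By the exact binomial test with Benjamini-Hochberg adjustment 17 of 17 members differed between the libraries, 13 toward replicate 1 and 4 toward replicate 2, both over all genes tested and adjusted over the list alone. Since 85.5% of all genes tested also differed, this count does not set the list apart. Col1a1 and Col1a2, which encode the chains of type I collagen, were at 77.2 and 122 CPM in replicate 1 and at 27.5 and 47.0 CPM in replicate 2. Genes of secretory granules were higher in replicate 2, with a median log2 ratio of 0.24 at percentile 98.2, and 19 of 24 members were higher there. That percentile singled the list out of the 16, so it does not test random scatter. By the same exact test with Benjamini-Hochberg adjustment 23 of 24 members differed, 18 of them toward replicate 2 and 5 toward replicate 1, and the count adjusted over the list alone was also 23. This count too stands against 85.5% of all genes tested and does not set the list apart. Cpe was at 2363 and 3437 CPM and Pcsk2, a prohormone convertase, at 669 and 1106 CPM in replicates 1 and 2. The endocrine transcription factors had a median log2 ratio of -0.05 at percentile 44.6. The hormones had a median of 0.22 at percentile 92.9.

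**Figure D3:**
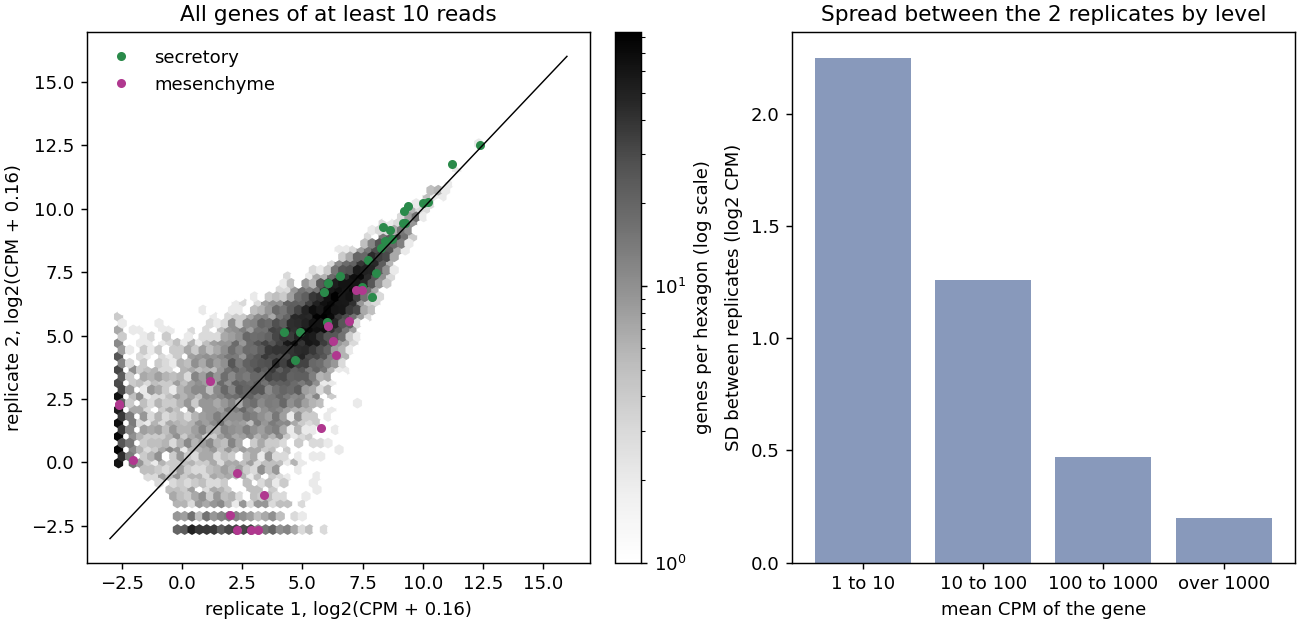
Left, log2(CPM + 0.16) of replicate 2 against replicate 1 for 13416 genes, shaded by genes per hexagon on a log scale, with secretory (green) and mesenchymal (purple) list members and the line of equality. Right, the SD between replicates in log2 CPM by mean CPM of the gene, which is 2.25 from 1 to 10 CPM and 0.20 above 1000 CPM.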

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

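Rn45s left out of the totals, the mesenchymal list without collagens and reads per kb with the full annotation were chosen only after the results were seen, and so was the basic transcript set used for the main reads per kb. The number of genes detected stayed within 1.5 times the main count, from 8784 at a limit of 5 CPM to 12017 without replicate 1, and the number of genes differing was between 11468 and 11699 under the other scalings and without a count filter, but 6394 when a 2-fold difference was also required. The Pearson correlation was 0.907 with no filter on low counts, 0.624 with at least 100 reads and 0.653 with a prior count of 0.5, and Spearman's rho was 0.902 with no filter and 0.765 with at least 100 reads; the unfiltered values include genes with no read in either library. The biological coefficient of variation was 0.777 for the trended dispersion at the median gene. The mesenchymal and secretory lists stayed outside the central 95% of random lists in every alternative run, and without collagens the mesenchymal median log2 ratio was -2.70. The semaphorin median turned from -0.27 to 0.75 with no count filter; the cause was not tested.

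The endocrine lists stayed above the 9 lists of other cell types they were compared with in all alternatives run. The difference of median log2 CPM moved by more than the replicate SD as follows. With a prior count of 0.5 it was 6.01 for the acinar, 11.37 for the endothelial, 11.34 for the immune and 12.93 for each of the erythroid, liver and gut lists. With members of at least 10 reads only it was 2.12 for the ductal, 5.05 for the acinar, 7.29 for the endothelial, 6.10 for the immune, 7.62 for the erythroid, 6.60 for the liver and 2.73 for the gut list, since this drops the members with fewer reads. Per kb of exon it was 2.73 for the ductal, 4.50 for the acinar, 8.27 for the immune, 8.42 for the erythroid, 9.12 for the liver and 8.72 for the gut list, and with the full annotation 2.79, 4.79, 8.71, 8.38, 9.21 and 8.60. Leaving out each replicate gave 5.96 to 5.99 for the acinar list.

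Counts of list members at or above 1 CPM in both libraries differed by over 1.5 times as follows. Without replicate 2 the count was 14 for the mesenchymal list (8 with both), 2 for the endothelial (1), 2 for the liver (1) and 4 for the sex-linked list (1). Without replicate 1 it was 3 for the endothelial (1), 3 for the neural crest (1) and 2 for the liver list (1). At a limit of 0.5 CPM it was 2 for the liver and 2 for the sex-linked list, and at 5 CPM it was 0 for the endothelial, erythroid, neural crest and liver lists and 1 for the immune list (2).

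Orders of close genes depended on exon length. Per kb, the log2 ratio of Neurog3 to Insm1 turned to 0.44 (0.32 with the full annotation), that to Nkx2-2 to 0.61 (0.68) and that to Cdkn1a to 0.71 (0.98). Leaving out each replicate gave -0.36 to 0.15 for Neurog3 to Cdkn1a, so this order was not settled. Ratios of Neurog3 to Myt1 and Rfx6 also rose per kb, to 1.93 (0.06 by CPM) and 2.38 (1.10). The correlations, the coefficient of variation, the genes differing and the list ratios need both libraries and have no value without a replicate. No paired analysis was possible because the series holds 1 group. Depth limits what a count of 0 allows, up to 0.241 CPM in replicate 1 and 0.248 CPM in replicate 2, and for 11468 of 13416 genes the libraries differed beyond counting error.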

Other observations

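The tests of mesenchymal transcripts, of imprinted genes, of counting error and of ribosomal protein genes, the last because the transcript set was changed after a first result, were chosen only after the result was seen.

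Several imprinted genes were abundant in the sorted cells. Peg10 was at 10145 ± 838 CPM, Gnas at 7429 ± 523 CPM, Peg3 at 3051 ± 182 CPM and Grb10 at 2450 ± 433 CPM (SD, n = 2), and these 4 prompted a list of 32 imprinted genes written after the most abundant genes had been seen. Of the others, Meg3 was at 1304 ± 283 CPM, Rian at 952 ± 46.4 CPM and Nnat at 844 ± 60.6 CPM, while no read of Snrpn or Phlda2 was counted. Of the 32 genes, 29 reached 1 CPM in both libraries, and the rest were left out of the test. With the 4 prompting genes left out, 25 detected members had a median of 85.8 CPM, against 37.3 CPM for all detected genes, at percentile 99.56 of 10000 random lists of detected genes. The hypothesis that imprinted genes as a class lie above other detected genes held in that test, though the list was made after these data were seen, and Dlk1 and Cdkn1c are also in lists described above. Members such as Airn and Igf2r, which overlap, are not independent, while the random lists drew genes independently, so the percentile may be too extreme. The random lists were also not matched on exon length. Over all detected genes the median was 20.8 CPM under 1 kb of exon and 54.5 CPM above 4 kb, so the test cannot separate imprinting from length. Airn and Igf2r overlap, as do Kcnq1ot1 and Kcnq1, so without a stated strand setting their counts are uncertain.

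The libraries differed by far more than counting error, with a mean squared Poisson z of 123.9 per gene where counting error alone gives about 1; this value describes the difference and does not test its cause. A trend on GC content and exon length explained 0.14% of the variance of the log2 ratio over 8993 genes (0.13% with the full annotation), which argues against such a bias. Few RNA molecules sampled and then amplified may account for it: the excess variance fell with level with a slope of -1.07 (bootstrap 95% interval -1.12 to -1.02) on a log scale, where sampling of molecules gives a slope near -1 and a constant variance 0. If that were the cause, about 49000 effective molecules per library would be needed, from 37000 to 59000 over 15 bins of expression. This is a model value and not a count. The fit took genes from 10 CPM, which in this model would hold few molecules, while the value and the slope near -1 assume many. The interval of the slope also lies wholly below -1, so the slope cannot settle the cause. No biological explanation was tested, since the series has 1 group, and a difference between embryos or dissections stays open.

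Mesenchymal transcripts were higher in replicate 1, with the list's median at percentile 0.13 of matched random lists; that value singled the list out of the 16, so it does not test random scatter, which stays open. Of the list's 17 members, 4 went the other way and were higher in replicate 2 beyond counting error. Dcn and Col3a1, chosen after their values were seen, were at 53.9 and 83.4 CPM in replicate 1 and 2.40 and 18.9 CPM in replicate 2. More mesenchymal cells or their RNA in replicate 1 could account for it, although the sort for GFP should remove such cells: 76.5% of 17 members of this list, picked for its direction, were higher in replicate 1 (exact Clopper-Pearson 95% interval 50.1 to 93.2), which lies between the 80% set for that explanation and the 60% set against it, both set after the result. Dlk1 is also known from islet cells. With 1 library on each side this stays open, and no biological explanation was tested.

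Gapdh, Ppia and Rps18, chosen after their values were seen, lay below the median of 37.3 CPM of genes that reached 1 CPM in both libraries, at 7.08 ± 2.62, 5.48 ± 2.25 and 14.2 ± 3.12 CPM, while Hprt was at 133 ± 37.4 CPM (SD, n = 2). The 77 ribosomal protein genes as a class did not lie below it, with a median of 60.2 CPM and a range from 0.0 to 1290.5 CPM. The 37.3 CPM is a median over all detected genes, so it cannot show whether ribosomal protein transcripts were counted below their true level. Reads shared with pseudogenes may have been lost, but the values go both ways: the share of 25-base words found in no other gene was 19.4% for Gapdh, 11.1% for Rps18, 68.7% for Ppia and 100% for Hprt, while Eef1a1 with 25.2% and Actb with 55.5% were at 1611 and 1800 CPM, and over the ribosomal protein genes this share and reads per kb had a Spearman rho of 0.148 (permutation p = 0.19, Benjamini-Hochberg adjusted p = 0.34), or -0.053 with the full annotation, which was run first (permutation p = 0.65). Short transcripts were not lost altogether, since the 7 of 10 hormone genes with under 1 kb of exon had a median of 693 CPM, but hormones are the most abundant list here and a lower yield of short transcripts stays open: over genes that reached 1 CPM in both libraries the median rose from 20.8 CPM under 1 kb of exon to 25.4, 31.9 and, above 4 kb, 54.5 CPM, which counts not divided by length also favour, while over the ribosomal protein genes rho between exon length and reads per kb was -0.126 (permutation p = 0.27, adjusted p = 0.38) and with the full annotation -0.295 (permutation p = 0.0097, adjusted p = 0.034), so it was below 0 by more than its spread only with the set that was later replaced, and a negative value is also favoured because reads per kb are divided by length. Of 7 correlations across these genes, which are not independent replicates, the others were 0.37 between unique words and CPM (permutation p = 0.0012, adjusted p = 0.0084), 0.22 between length and CPM (permutation p = 0.056, adjusted p = 0.13) and 0.01 between unique words over all transcripts and reads per kb (permutation p = 0.93).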
